A study of Arabidopsis thaliana with 10 samples.

How the data were processed

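Small RNA of 10 libraries, 1 library per group, was analysed from the sequence lists and gene tables that the authors deposited. Per the labels' protocols, RNA of about 18 to 30 nt was selected on gels before library preparation with a commercial small RNA kit. In the sequence lists the deposited values are raw counts of reads, 1 count for each distinct sequence, with identical reads already collapsed by the authors and the adapter no longer present. The trimming tool and its settings are not given in the sources used here. The lists also hold reads that do not match the genome, and in 6 libraries up to 40578 reads with an undetermined base. The second kind of table the authors deposited gives a signal per TAIR10 gene and read length in a column headed RPM. Its values sum to between 1100998 and 3377820 in each library, above 1000000, so it was treated as a signal of unstated denominator and used only as an alternative. Per the submitters' processing notes, Bowtie and TAIR10 were used, with no version given, and the mismatches allowed and the handling of repeated matches are not given in the sources used here.

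From the counts, each sequence of 18 to 30 nt was matched exactly to every site of the TAIR10.1 assembly (NCBI RefSeq), which includes both organelles, with code written for this work (Python 3.11.15, numpy 2.4.6, numba 0.67.0, pandas 2.3.3). A sequence with several sites was shared equally over them. Matched reads were taken out of the denominator where they lay in an organelle or in rRNA, tRNA, snRNA or snoRNA. Nuclear ribosomal repeats were masked from 5500 bp before to 6300 bp after the start of each long annotated rRNA gene, a range set after the data were examined. The remaining reads are the denominator of RPM. Gene types were taken from the authors' deposited table and coordinates from TAIR10.1, with 3856 TE genes covering 9357789 bp. Mature miRNAs were counted as identical sequences. Reads of closely related TE genes, or of miRNAs with several loci, cannot be assigned to 1 copy.

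TE genes were grouped into families by sequence with BLAST 2.17.0, joining a gene to a longer one at 80% identity over 80% of its length and at least 80 bp. This gave 1738 families, 1259 of a single gene and the largest of 155. The definition was settled after the data were examined, because a first version by single linkage joined unrelated genes. A TE gene was said to carry the motif where TGGTATCAGAGC lay in it or within 1500 bp upstream on its strand. There were 430 such sites in the genome, 290 of them at 287 TE genes in 180 families. TE superfamilies and ATHILA elements were planned as lists and are not analysed here. The lists of 32 conserved miRNAs, 3 DCL4-dependent miRNAs, 6 TAS loci and 2 miR845 sequences, the comparisons, the rule for named items and the first alternatives were fixed before the data were examined. Transcripts of the mutated genes are not measured by this assay, so the genotypes could not be checked on their own genes.

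Ratios of RPM between 2 libraries carry exact conditional binomial 95% intervals, and shares carry exact Clopper-Pearson intervals (scipy 1.17.1). A value under 1 read was treated as 0 and given as a bound against 3 reads. With 1 library per group there are no replicates, and no test across libraries was run. An additive fit of background and MIR845, or of dcl1 and dcl2dcl4, would leave 1 residual degree of freedom by taking the interaction as error, and was not run. TE families needed 200 reads of 21-22 nt in 1 of the 2 libraries, and miRNAs 100 reads. An item could thus enter through its higher or deeper library alone, which favours that side in the counts. Named for each comparison were miR845a and miR845b, up to 5 listed miRNAs and 5 TE families per direction with the most extreme ratios of at least 2-fold, the 5 TE families with the most reads, and the TAS loci. Annotated miRNAs outside the lists are named in the report only where it says so. Ranking added 0.5 reads to both sides. A list's median log2 ratio was set against 10000 random lists of the same size matched on mean level, as a description of these libraries, where it had at least 5 measured members. There were 9 comparisons, and that of Ler with Col pollen was added after the data were examined.

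Alternatives used all matched reads or 37 listed miRNAs as the denominator, uniquely matching reads, miRNA ends within 1 nt, distinct sequences, a minimum of 50 reads and single TE genes. A denominator without protein-coding genes and the authors' deposited signal were added later. The code was tested on simulated data. All 60 sequences checked had the sites that a text search found. Ler MIR845 over Ler pollen was simulated with 272 families and independent Poisson counts, the model that the intervals assume. Reads that are amplified or shared between families were thus not covered. The 95% interval held the true ratio in 48 of 50 families at 0.25, 48 of 50 at 0.5, 65 of 72 at 1, 45 of 50 at 2 and 47 of 50 at 4. The median estimates were 0.250, 0.495, 1.02, 1.99 and 3.93. Of 20 unchanged lists 19 fell between percentiles 2.5 and 97.5, and all 20 lists raised 2-fold lay above. Figures were drawn with matplotlib 3.10.9.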

Results

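Small RNAs were sequenced from Arabidopsis thaliana pollen and leaf to ask which enzymes make the small interfering RNAs (siRNAs) of transposable elements (TEs) in pollen, and how they relate to the microRNA miR845. There were 10 libraries, with 1 library per group. The strain Col-0 gave 6 of them: leaf, sorted pollen of the wild type, sorted pollen of dcl1, dcl2dcl4 and dcl1dcl2dcl4, and pollen of nrpd1a. The strain Ler-0 gave the other 4: Ler, Ler MIR845, osd1_2 and osd1_2 MIR845 pollen, where MIR845 stands in the label and its construct is not described. Dicer-like proteins (DCL) process double-stranded RNA into small RNAs. DCL1 makes most microRNAs, DCL4 and DCL2 make siRNAs of 21 and 22 nt, and NRPD1A is the largest subunit of RNA polymerase IV, which starts the pathway of 24-nt siRNAs. Mutants of the gene OSD1 skip the second meiotic division and form diploid pollen, but the labels do not say whether osd1_2 names an allele or a ploidy, and it is used here only as a label. The protocol in the labels describes dcl1 plants as heterozygous and sorts their pollen by a fluorescent sensor of miR845b, so the low miR845 level in the dcl1 and dcl1dcl2dcl4 libraries is not independent of the sort. The same protocol text is attached to every library, and the nrpd1a and Ler-0 libraries are not labelled as sorted.

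The libraries listed 2284317 reads for Col sorted pollen, 3827648 for dcl1, 2728530 for dcl2dcl4, 2737452 for dcl1dcl2dcl4, 3682486 for nrpd1a and 1922708 for leaf. The Ler-0 libraries were deeper, with 90572271 reads for Ler, 69643795 for Ler MIR845, 63179385 for osd1_2 and 46470013 for osd1_2 MIR845. Between 76.2% of reads in dcl1dcl2dcl4 and 94.3% in nrpd1a matched the genome exactly. Ribosomal RNA fragments made up 64.9% of matched reads in Col sorted pollen, 89.3% in Ler, 85.4% in nrpd1a and 26.9% in leaf. Plastid reads made up 24.3% of matched reads in leaf, 2.28% in Col sorted pollen, 0.716% in Ler, 2.14% in Ler MIR845, 4.95% in osd1_2 and 2.71% in osd1_2 MIR845. They made up 2.65% in dcl1, 1.38% in dcl2dcl4, 4.74% in dcl1dcl2dcl4 and 0.969% in nrpd1a. Levels are reads per 1000000 genome-matched reads that were neither organellar nor structural RNA (RPM). That denominator held 389508 reads in Col sorted pollen, 116375 in dcl1dcl2dcl4, 186532 in nrpd1a, 791715 in leaf and between 5001162 and 6281218 in the Ler-0 libraries. Fragments of protein-coding genes made up 44.5% of it in Ler, 53.3% in nrpd1a and from 12.1% to 23.2% in the other libraries. No difference has a replicate check. The 95% intervals are exact binomial intervals that compare libraries, not genotypes, and cover counting error only, since the amplified reads carry no molecular identifiers.

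Pollen and leaf differed in the sizes of their TE siRNAs. Col sorted pollen held 33520 RPM of 21-22-nt reads at TE genes (95% interval 32950 to 34080) and leaf held 3158 RPM, a ratio of 10.6 (10.2 to 11.1). The excess was larger at 22 nt, with a ratio of 16.7, than at 21 nt, with 5.95, whereas the level at 24 nt was close, with a ratio of 1.07, and with all matched reads as the denominator every ratio below 2.33 lies under 1. TE reads of 21-22 nt equalled 1.03 times those of 24 nt in pollen and 0.105 times in leaf. Of all matched reads, 14.8% were 21 nt, 12.8% were 22 nt and 13.3% were 24 nt in Col sorted pollen, against 21.3%, 9.27% and 21% in leaf. Among reads outside organelles and structural RNA, 24-nt reads made up 19.8% in pollen and 36.6% in leaf.

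**Figure D1:**
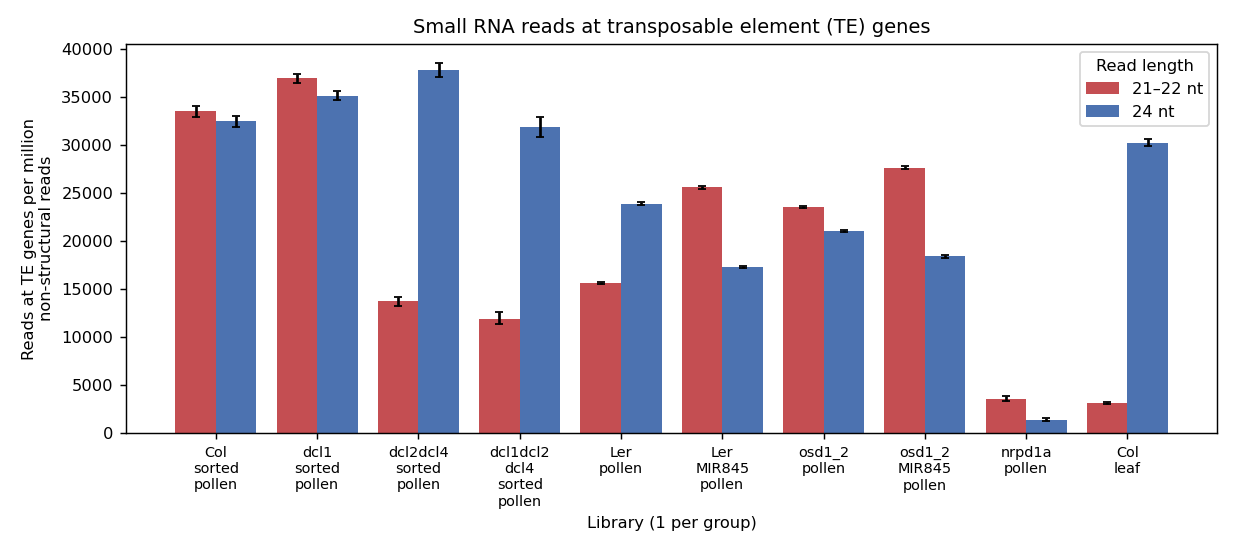
Level of 21-22-nt and 24-nt reads at TE genes in each of the 10 libraries, in RPM, with bars starting at 0 and 95% exact binomial intervals. The 21-22-nt level was 33520 RPM in Col sorted pollen, 3158 in leaf and 3600 in nrpd1a pollen, and the 24-nt level in nrpd1a pollen was 1448.

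All 8 measured TE families stood at least 2-fold higher in pollen than in leaf under each of 4 denominators. A family here is a set of TE genes of similar sequence, named after its longest gene. The family of AT2G01029 (18 TE genes; the named gene at chromosome 2, 28465 to 38652, TAIR10.1) had a ratio of 85.1 (51.5 to 160). The family of AT5G29075 (21 genes; chromosome 5, 11136149 to 11146651) had 53.1 (31.6 to 91.8), AT1G40113 (22 genes; chromosome 1, 15160610 to 15166681) had 45.3 and AT4G05585 (52 genes; chromosome 4, 2867197 to 2876145) had 15.6. The largest family, that of AT1G40101 with 155 genes (chromosome 1, 15063543 to 15076496), had 17.5 (13.1 to 24.3).

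MicroRNAs separated the tissues in the other direction. Of 18 measured conserved miRNAs, 13 were at least 2-fold lower in pollen and 1 was higher. The miRNA 167a, a regulator of auxin response factors, had 0 reads in pollen against 1567 RPM in leaf, at least 204-fold lower. The level of miR159a, which targets MYB factors, was 97.9-fold lower (23110 RPM in leaf, 236 in pollen), while miR156a, which targets SPL transcription factors, was 25.3 times higher in pollen (23.5 to 27.2). With listed miRNAs as the denominator 10 of the 18 were at least 2-fold lower, and with all matched reads 17. Both miR845a (CGGCUCUGAUACCAAUUGAUG; AT4G23387, chromosome 4, 12217457 to 12217477) and miR845b (UCGCUCUGAUACCAAAUUGAUG; AT4G23375, chromosome 4, 12214086 to 12214107) were at 0 reads in leaf. Pollen held 1356 and 1127 RPM of them, together at least 655-fold higher. Trans-acting siRNA loci, whose siRNAs depend on miRNA-guided cleavage, were lower in pollen: TAS1A had a ratio of 0.242, TAS1C 0.270, TAS2 0.192 and TAS3 0.0298. TAS1B had 0.550, which turned to 1.51 with listed miRNAs as the denominator. TAS4 had too few reads for a ratio.

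**Figure D2:**
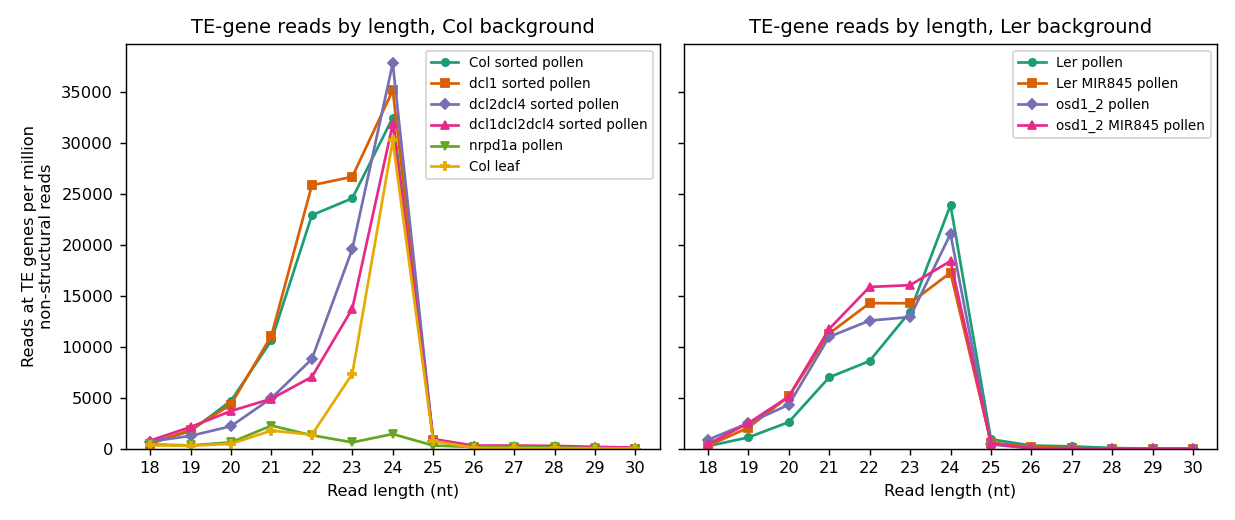
Level of TE reads by length in nt, in RPM, for the Col-0 libraries in one panel and the Ler-0 libraries in the other. Reads of 23 nt, next to the named sizes, reached 24560 RPM in Col sorted pollen and 7347 RPM in leaf.

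Sorted dcl1 pollen kept TE siRNAs near the wild-type level and had lower levels of most measured conserved miRNAs. The level of 21-22-nt TE reads was 36940 RPM, 1.1 times that of the wild type (1.08 to 1.13), and the 24-nt ratio was 1.08. The listed miRNAs together were at 0.280 times the wild-type level, with 8 of 11 measured conserved miRNAs at least 2-fold lower and 0 at least 2-fold higher, or 7 and 3 with listed miRNAs as the denominator. Examples were miR156a at 0.0243, miR157a at 0.0380 and miR403, which targets AGO2, at 0.0575. By contrast, miR166a (0.840), miR159a (0.998) and miR390a (1.01) stayed near the wild-type level, with 0.5 reads added to both sides. The miR845 sequences, whose sensor the sort read, had 14 reads, 113-fold lower than in the wild type (ratio 0.00888, 0.00484 to 0.0150), or 0.0311 relative to the other listed miRNAs. Of 16 TE families, 13 were above 1, and 1 was at least 2-fold higher: AT1G50810 (3 genes; chromosome 1, 18828868 to 18832972) at 2.30 (1.71 to 3.12), with 342 against 149 RPM. The most abundant families lay between 0.820 (0.737 to 0.913) for AT2G01029 and 1.22 (1.1 to 1.35) for AT4G05585.

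The trans-acting siRNAs of TAS1A had a ratio of 0.0498, TAS1B 0.115, TAS1C 0.141 and TAS2 0.157 in dcl1 pollen. TAS3 had 0.750, which its interval (0.437 to 1.30) does not separate from 1. TE genes with a 12-nt motif complementary to miR845 (TGGTATCAGAGC, in the primer binding site of many retrotransposons) had a ratio of 1.09 against 1.11 for those without it. The median ratio of 6 families with the motif was 1.2, at percentile 97.2 of 10000 random lists of families, with percentile 98.7 for 13 families at a minimum of 50 reads, above the range of random lists. With listed miRNAs as the denominator, itself lower in dcl1 pollen, every ratio is multiplied by 3.58: the TE ratio is then 3.94, all 16 families are at least 2-fold higher and AT2G01029 turns to 2.93 and TAS3 to 2.68.

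The dcl2dcl4 library had lower 21-22-nt TE siRNAs. The 21-22-nt level was 13760 RPM, 0.411 times the wild type (0.395 to 0.427), with 0.467 at 21 nt, 0.384 at 22 nt and 1.17 at 24 nt. All 8 measured families were at least 2-fold lower (6 of 8 with listed miRNAs as the denominator). They ranged from 0.345 (0.282 to 0.418) for AT2G01029 to 0.492 (0.411 to 0.586) for AT4G05585, with AT3G42256 (47 genes; chromosome 3, 14423424 to 14432589) at 0.357. The trans-acting siRNAs, which need DCL4, had ratios below those of the 8 measured families: TAS1A had 0.00825, TAS1B 0.0135, TAS2 0.0188 and TAS1C 0.0300. TAS3 had 0.0602, from 1 read against 27, and its interval (0.00147 to 0.365) overlaps that of AT2G01029.

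The listed miRNAs of dcl2dcl4 pollen were together at 0.929 times the wild-type level, with 4 of 10 conserved miRNAs at least 2-fold lower and 2 higher. Examples were miR158a at 0.141 and miR403 at 0.263, against miR168a, which targets AGO1, at 4.98 (4.4 to 5.66) and miR161.1 at 2.31. The miR845 level was 0.393 times the wild type (0.340 to 0.454). With all matched reads as the denominator, where mitochondrial fragments made up 18.1% against 6.50% in the wild type, the TE ratio is 0.233 and every ratio below 1.76, the 24-nt one included, lies under 1. Reads of 29 nt made up 12.3% of the main denominator in dcl2dcl4 and 10.2% in dcl1dcl2dcl4, against 0.0788% in the wild type. Both mutant lists held 0 reads with an undetermined base, against 3911 in the wild type. A difference in library preparation or read processing was not tested.

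Sorted dcl1dcl2dcl4 pollen had both classes lower. TE reads of 21-22 nt were at 11950 RPM, 0.357 times the wild type (0.337 to 0.377), with a 24-nt ratio of 0.981. Of 8 measured families, 7 were at least 2-fold lower. AT5G29075 was 7.44-fold lower and AT2G01029 7.11-fold lower, whereas AT1G40101 had a ratio of 0.413 (0.307 to 0.555). Of 10 conserved miRNAs, 8 were at least 2-fold lower and 1 higher: miR156a had a ratio of 0.0167, miR403 0.0351 and miR157a 0.0377, against miR159a at 5.06 (3.86 to 6.66). Leaf held 23110 RPM of miR159a, and plastid reads made up 4.74% of matched reads in this library against 2.28% in the wild type. TAS1C, also abundant in leaf (17810 RPM), was at 68.7 RPM. Whether leaf RNA contributed to the miR159a level was not tested. The miR845 level rested on 6 reads and was 48.2-fold lower (ratio 0.0208, 0.00760 to 0.0454), or 0.0902 relative to the other listed miRNAs. With listed miRNAs as the denominator every ratio is multiplied by 4.43, the TE ratio turns to 1.58 and 6 of the 8 families stand above 1, while with all matched reads the TE ratio is 0.100.

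Set against dcl2dcl4, the dcl1dcl2dcl4 library had a TE 21-22-nt ratio of 0.869 (0.815 to 0.925), with 0.989 at 21 nt, 0.801 at 22 nt and 0.842 at 24 nt. AT2G01029 had a ratio of 0.408 (0.253 to 0.626) and AT5G29075 had 0.287 (0.155 to 0.472). For AT4G05585 (0.771, 0.562 to 1.03), AT1G40101 (1.07, 0.760 to 1.52) and AT5G33533 (28 genes; 1.07, 0.741 to 1.54) no difference was detectable at this depth. Conserved miRNAs were lower in 9 of 10 cases, with miR156a at 0.0373, miR161.1 at 0.0381 and miR168a at 0.0445, and miR159a was higher at 2.78. The miR845 ratio was 0.0528 (0.0192 to 0.117), or 0.216 relative to the other listed miRNAs, and TAS1C (0.477, 0.194 to 1.07) and TAS2 (1.37) could not be told from 1. TE genes with the motif had a ratio of 0.726 against 0.897 for the rest. The TE ratio was 0.966 (0.907 to 1.03) without protein-coding fragments, where no difference was detectable, 0.430 with all matched reads as the denominator, and turned to 3.57 with listed miRNAs, where AT2G01029 was at 1.68 and AT5G29075 at 1.18.

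Pollen of nrpd1a had low TE siRNAs at 21, 22 and 24 nt. The 21-22-nt level was 3600 RPM, 0.107 times that of Col sorted pollen (0.0993 to 0.116), and the 24-nt level was 1448 RPM, a ratio of 0.0446. The ratio was 0.214 at 21 nt and 0.0580 at 22 nt. TE reads of 28 nt, which were rarer, stood at 139.8 RPM against 10.9, from 26.1 and 4.3 reads. This was not particular to TEs or to nrpd1a. Among all reads outside organelles and structural RNA, 28-nt reads made up 3.75% in nrpd1a and 0.341% in Col. The dcl1dcl2dcl4 library held 285 RPM of 28-nt TE reads. Of 9 measured families, 8 were at least 2-fold lower: AT1G40101 by at least 67.9-fold, AT2G09187 (31 genes; chromosome 2, 3639603 to 3646073) by at least 41.1-fold, and AT4G05585 with a ratio of 0.0194 (0.00612 to 0.0444). Families with less depletion were AT2G01029 at 0.0631 and AT5G29075 at 0.116. AT5G32002 (5 genes; chromosome 5, 11474497 to 11478579) stood at 1140 RPM against 490, a ratio of 2.33 (1.91 to 2.85), which turned to 0.629 with all matched reads as the denominator.

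The miR845 level of nrpd1a pollen was 0.875 times that of Col sorted pollen (0.777 to 0.983) and turned to 1.28 relative to the other listed miRNAs. Of 9 conserved miRNAs, 1 was at least 2-fold lower (miR156a, 0.330) and 0 higher, and with all matched reads as the denominator all 9 were lower. Without protein-coding fragments 3 were at least 2-fold higher and 0 lower, and with listed miRNAs 2 and 1. TAS1A had a ratio of 1.80, TAS1B 2.09 and TAS1C 2.04, which turned to 0.485, 0.564 and 0.552 with all matched reads, and TAS2 had 0.993. The nrpd1a library is not labelled as sorted and the Col library is, and the TE ratio was 0.0290 with all matched reads, 0.157 with listed miRNAs and 0.178 without protein-coding fragments.

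Ler MIR845 pollen had more miR845b and more 21-22-nt TE reads than Ler pollen. The miR845 level was 826 RPM against 7.76, a ratio of 106 (77.7 to 150), which was 56.4 relative to the other listed miRNAs and 44.0 with ends within 1 nt. All of it was miR845b, with 5185 reads against 38, while miR845a had 0 against 1. TE reads of 21-22 nt were at 25580 RPM against 15610, a ratio of 1.64 (1.62 to 1.65), nearly equal at 21 nt (1.61) and 22 nt (1.66), and the 24-nt ratio was 0.723, which turned above 1 with all matched reads as the denominator, as does every ratio over 0.605. The direction of the 21-22-nt ratio turned with listed miRNAs as the denominator (0.864), it was 1.18 without protein-coding fragments and 2.71 with all matched reads. That turn leaned on miR166a, which made up 57680 of the 144900 RPM of listed miRNAs in Ler MIR845 and 16080 of 76400 in Ler. The ratio of miR166a itself was 3.59, above the 1.90 of the listed miRNAs together. Without it the TE ratio would thus lie above 0.864. Its value was not computed, so whether the turn holds without miR166a is not known.

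**Figure D3:**
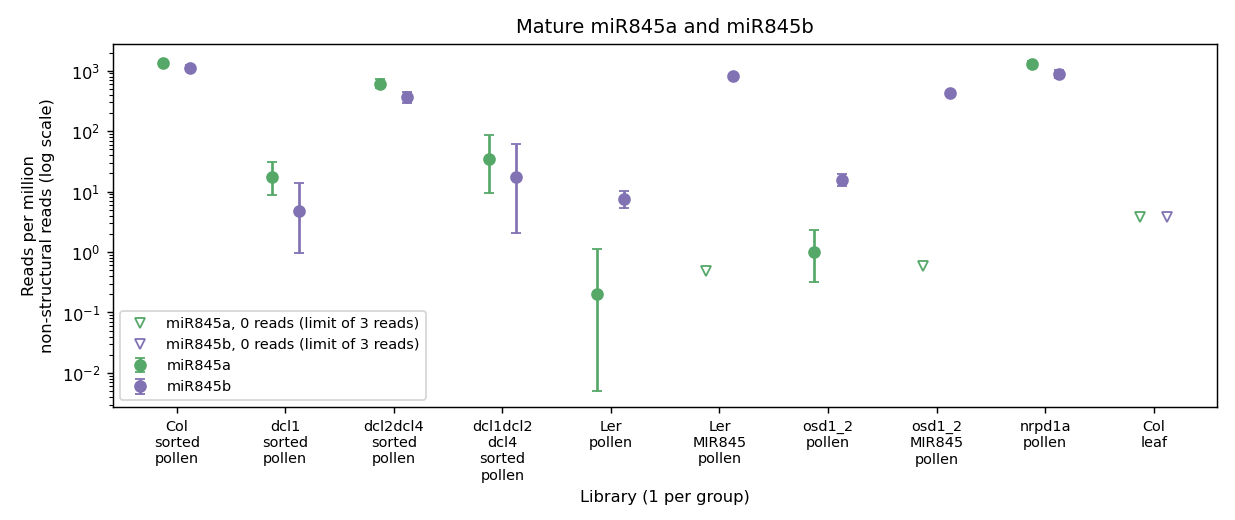
Level of miR845a and miR845b in each library, in RPM on a log axis, with 95% exact binomial intervals; open triangles mark libraries with 0 reads at the level of 3 reads. In the Ler-0 libraries miR845b was at 7.56 RPM in Ler, 15.6 in osd1_2, 826 in Ler MIR845 and 434 in osd1_2 MIR845.

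Of 99 measured TE families, 96 were above 1 and 22 were at least 2-fold higher in Ler MIR845 pollen, with a median ratio of 1.62. AT1G36790 (5 genes; chromosome 1, 13936159 to 13938917) had 6.07 and AT5G33382 (1 gene; chromosome 5, 12616563 to 12621331) had 4.56, both from low levels. Abundant families were AT3G29775 (4 genes, all with the motif; chromosome 3, 11665356 to 11669402) at 2.38 (2.31 to 2.44), AT1G46120 (1 gene; chromosome 1, 17203685 to 17207422) at 2.29, AT1G50810 at 2.22 (2.11 to 2.34), and AT4G05585 at 1.34, which turned to 0.706 with listed miRNAs and 0.964 without protein-coding fragments. AT5G45605 (2 genes; chromosome 5, 18490916 to 18495757) had 0.852, which turned to 1.41 with all matched reads. The number of families above 1 was 77 without protein-coding fragments, 26 with listed miRNAs and 99 with all matched reads, and the number at least 2-fold higher was 4, 2 and 90.

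Whether TE genes with the motif stood apart in Ler MIR845 pollen depended on the setting. TE genes with it had a ratio of 1.70 and those without it 1.61. The total with the motif leaned on AT3G29775 and AT1G46120. They held 7065 and 3301 of its 28197 reads in Ler, and 20982 and 9447 of 59867 in Ler MIR845. Both families had ratios (2.38 and 2.29) above 1.70, so the ratio of the other TE genes with the motif was lower. Its value, and whether it still lay above 1.61, was not computed. The median ratio of 21 families with the motif was 1.71, at percentile 83.2 of random lists, with percentile 99.8 for 70 families at a minimum of 50 reads, above the range of random lists, and 3.22 for single TE genes. MicroRNAs were also higher: the listed miRNAs had a ratio of 1.90, and 10 of 19 conserved miRNAs were at least 2-fold higher, among them miR171a, a regulator of GRAS factors, at 24.5, miR163 at 23.6, miR159a at 17.6 and miR398b, which targets copper superoxide dismutases, at 12.3. Outside the lists, and chosen after their values were seen, miR851-5p had 59.5 (20.1 to 291), miR780.2 had 26.9 (8.96 to 133), each from 3 reads in Ler, and miR166a-5p had 23.1 (10.4 to 63.7). Among conserved miRNAs the median ratio was 2.68, at percentile 99.7 of random lists of miRNAs, in a library with 2.14% plastid reads against 0.716% in Ler. With listed miRNAs as the denominator 8 were at least 2-fold higher and 2 at least 2-fold lower, and with all matched reads 14 and 0. TAS3 had 7.48, and TAS1A (1.43), TAS1B (1.68), TAS1C (1.49) and TAS2 (1.84) all turned below 1 with listed miRNAs as the denominator. miR839, the measured one of 3 DCL4-dependent miRNAs, had 1.24, and every ratio below 1.9 turns under 1 with listed miRNAs.

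Pollen labelled osd1_2, without MIR845 in the label, differed from Ler pollen in a like way, in a comparison that shares the Ler library with the one before. TE reads of 21-22 nt were at 23550 RPM, a ratio of 1.51 (1.50 to 1.52), with 0.881 at 24 nt, and with all matched reads as the denominator every ratio over 0.669 lies above 1. Of 67 measured families, 65 were above 1 and 7 at least 2-fold higher: AT5G33382 at 5.27, AT1G36790 at 3.78, AT3G29775 at 2.54 and AT1G46120 at 2.49, while AT2G01029 (1.25) and AT4G05585 (1.27) turned to 0.511 and 0.518 with listed miRNAs. AT5G45605 had 0.959 and turned to 1.43 with all matched reads. Families above 1 numbered 43 without protein-coding fragments, 5 with listed miRNAs and 67 with all matched reads, and those at least 2-fold higher 2, 1 and 46. The TE ratio was 1.09, 0.617 and 2.26 under these settings. Among listed miRNAs, miR166a alone made up 96340 of 186700 RPM in osd1_2 pollen, against 16080 of 76400 in Ler. It had a ratio of 5.99, where the listed miRNAs together had 2.44. Without it the TE ratio would thus lie above 0.617, and its value was not computed. The miR845 ratio was 2.14 (1.45 to 3.22), from 83 reads, and turned to 0.875 relative to the other listed miRNAs.

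Conserved miRNAs were again higher in osd1_2 pollen, 10 of 19 by at least 2-fold, in the library with the highest plastid share of the Ler-0 libraries, with a median ratio of 3.56 at percentile 99.9 of random lists. With listed miRNAs as the denominator 9 were at least 2-fold higher and 6 at least 2-fold lower, and with all matched reads 12 and 0. The ratio was 32.8 for miR163, 17.1 for miR171a, 8.45 for miR159a and 7.42 for miR390a, which starts TAS3 siRNAs. TAS3 itself had 5.15, TAS2 had 1.73, which turned to 0.709 with listed miRNAs as the denominator, and miR839 had 0.859, which turned above 1 with all matched reads. TE genes with the motif had a ratio of 1.67 against 1.42, and 13 families with the motif had a median of 1.36, at percentile 17.8, with percentile 93.0 for 59 families at a minimum of 50 reads and 58.4 for single TE genes. The ratio of 1.67 leaned on AT3G29775 and AT1G46120. They held 17820 and 8169 of the 46786 reads at TE genes with the motif in osd1_2, and 7065 and 3301 of 28197 in Ler. Both families had ratios above 1.67, so the ratio of the other TE genes with the motif was lower. Whether it still lay above 1.42 was not computed.

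**Figure D4:**
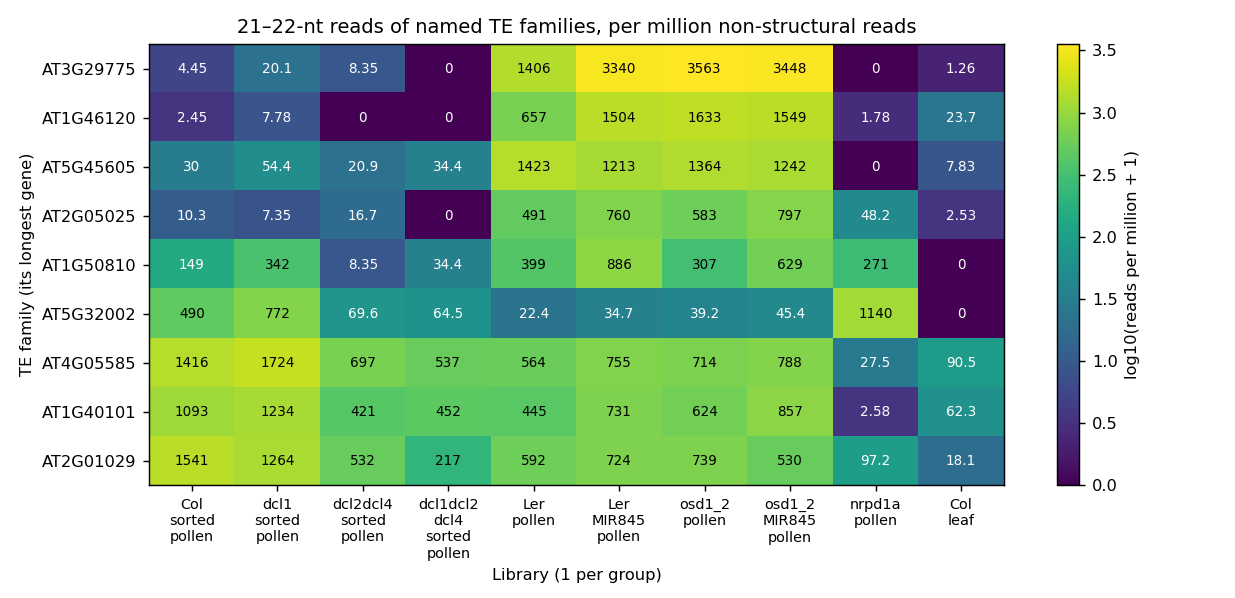
Heat map of log10 of (RPM + 1) of 21-22-nt reads for 9 named TE families in the 10 libraries. AT3G29775 was at 1406 RPM in Ler pollen, 3340 in Ler MIR845, 3563 in osd1_2 and 4.45 in Col sorted pollen.

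Between the osd1_2 libraries, MIR845 went with higher miR845b. The miR845 level was 434 RPM against 16.6, a ratio of 26.1 (21 to 32.9), or 13.5 with ends within 1 nt. TE reads of 21-22 nt were at 27620 RPM against 23550, a ratio of 1.17 (1.16 to 1.18), larger at 22 nt (1.26) than at 21 nt (1.07). Of 92 measured families, 79 were above 1 and 1 was at least 2-fold higher: AT1G50810 at 2.05 (1.93 to 2.18), with 629 against 307 RPM. AT1G40101 had 1.37 and AT4G05585 1.1, while AT3G29775 (0.968), AT1G46120 (0.948) and AT5G45605 (0.911) turned to 1.29, 1.26 and 1.21 with all matched reads as the denominator. The number at least 2-fold higher was 18 with all matched reads, 7 with listed miRNAs and 0 without protein-coding fragments.

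TE genes with the motif had a ratio of 1.02 and those without it 1.27 in this comparison. AT3G29775 and AT1G46120 held 17529 and 7876 of the 48549 reads at TE genes with the motif in osd1_2 MIR845. The median ratio of 18 families with the motif was 1.13, at percentile 0.125 of random lists, with percentile 55.9 for 74 families at a minimum of 50 reads and 5.64 for single TE genes, where the median turned to 0.971. The listed miRNAs were at 0.853, above 1 with all matched reads as is every ratio over 0.751, and 1 of 20 conserved miRNAs was at least 2-fold higher (miR159a, 2.09). Their median of 1.03 lay at percentile 16.5. Outside the lists, and chosen after their values were seen, miR780.2 had a ratio of 111 (19.6 to 4429), from 113 reads against 1, an interval that holds the 27.8 of miR845b, while miR399f had 2.90 (2.14 to 3.98) and miR827 had 2.53 (1.94 to 3.34). miR839 had 2.14 (1.80 to 2.56), TAS3 had 1.95 and TAS1A 1.31.

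The TE ratio of MIR845 in osd1_2 was 0.716 times that in Ler (0.707 to 0.724), and the miR845 ratio was 0.245 times (0.167 to 0.360), both intervals by a Poisson approximation on the log scale. The first turned to 1.59 with listed miRNAs as the denominator, and the second was 0.544 relative to the other listed miRNAs. Of 91 families measured in both backgrounds, 66 were above 1 in both with the intervals apart from 1, 8 differed in direction and 1, AT1G50810, was at least 2-fold higher in both. These counts followed the denominator: with all matched reads they were 85, 1 and 17, with listed miRNAs 12, 37 and 1, and without protein-coding fragments 34, 3 and 0.

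**Figure D5:**
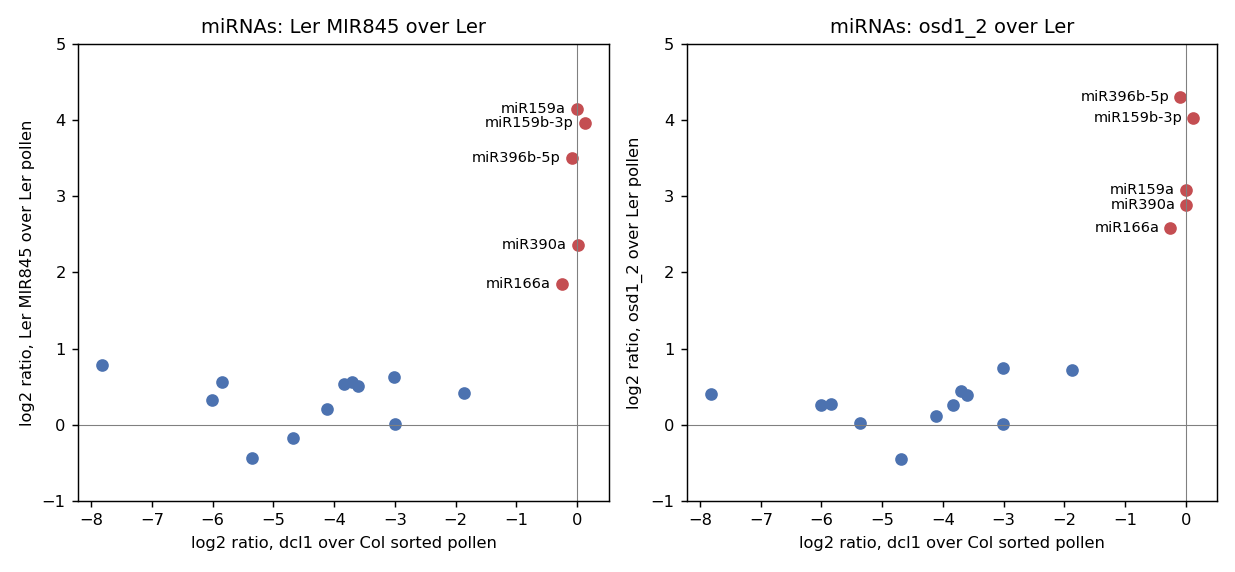
Log2 ratio of 17 miRNAs in dcl1 over Col sorted pollen against that in Ler MIR845 over Ler and in osd1_2 over Ler pollen, 1 point per miRNA. The 5 miRNAs with dcl1 ratios of 0.840 to 1.09 had ratios of 3.59 to 17.6 in Ler MIR845 over Ler pollen, and the other 12 had ratios of 0.741 to 1.73.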

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

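All tests of explanations in this part were chosen after the results were seen. The results here stood out because MIR845 libraries differed from their partners in opposite directions in the Ler and osd1_2 backgrounds with the main denominator; with 1 library each, the difference was not tested. For AT3G29775 the ratio was 2.38 in Ler and 0.968 in osd1_2, a ratio of ratios of 0.407. For AT1G46120 it was 2.29 and 0.948, or 0.414. For AT5G33382 it was 4.56 and 0.761, or 0.167. For miR163 it was 23.6 and 0.681, or 0.0288, and for the listed miRNAs together 1.90 and 0.853, or 0.450. The listed miRNAs leaned on miR166a, which had 3.59 and 0.735. The opposite directions depend on the denominator. All 5 kept them without protein-coding fragments, but with all matched reads only miR163 did (39.1 and 0.908), where AT3G29775 was at 1.29, AT1G46120 at 1.26, AT5G33382 at 1.01 and the listed miRNAs at 1.14 in osd1_2. With listed miRNAs as the denominator, miR163 (12.5 and 0.798) was again the only one of the 5 that differed in direction with both intervals apart from 1. The direction was not particular to miR163. With the main denominator it was shared by miRNAs outside the 5, such as miR396b-5p (11.4 and 0.715), miR390a (5.16 and 0.685) and miR408 (4.22 and 0.530). The miRNAs miR399f (0.481 and 2.90) and miR157a (0.885 and 1.08) went the other way round. These were not set against the other denominators here.

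The pattern weighed is a higher 21-22-nt level of all TE genes together in Ler MIR845 than in Ler pollen, not that of the flagged families. Those were each lowest in Ler. The order here is Ler, then Ler MIR845, osd1_2 and osd1_2 MIR845. AT3G29775 stood at 1406 RPM against 3340, 3563 and 3448, and AT1G46120 at 657 against 1504, 1633 and 1549. AT5G33382 had 54 reads against 308, 283 and 219. Their opposite directions thus go with a low value in the Ler library. For miR163 and the listed miRNAs no explanation was tested. Added leaf RNA would lower the level, because leaf held 0.202 times that of Ler pollen. Action of miR845 at TE genes with its motif is argued against as the whole cause. TE genes without it had a ratio of 1.61, and the ratio of the MIR845 ratio of TE genes with the motif to that of the others was 1.06 in Ler and 0.802 in osd1_2. The totals with the motif leaned on AT3G29775 and AT1G46120, at 7065 and 3301 of 28197 reads in Ler. Their ratios (2.38 and 2.29) raised the value of 1.06 in Ler. At a minimum of 50 reads, however, families with the motif lay at percentile 99.8 of random lists in Ler, so a part stays open, with sites outside the annotated genes and their upstream 1500 bp not covered. A smaller share of mRNA fragments in the denominator stays open: without protein-coding fragments the ratio of 1.64 fell to 1.18 (1.17 to 1.19), and with 1 library each the rest cannot be told apart from variation between libraries. A property of the Ler library alone also stays open. Pollen of osd1_2, with no MIR845 in its label, reached 0.833 of the log2 ratio. The share was 0.521 without protein-coding fragments, 0.621 with the authors' deposited signal, 0.692 with uniquely matching reads and 0.818 with all matched reads. With listed miRNAs as the denominator both libraries were below Ler, a result that leaned on miR166a and was not computed without it. An effect of MIR845 on all TEs, or of what osd1_2 stands for, was not tested.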

How the results depend on the processing

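The denominator without protein-coding genes and the authors' deposited signal were chosen after the data were seen, and the other settings before. Of 88 alternatives for the comparisons, 31 kept the value within its interval, 49 moved it in the same direction and 8 turned the direction. No paired analysis was run. TE 21-22-nt ratios are given in the order pollen over leaf, dcl1, dcl2dcl4 and dcl1dcl2dcl4 over Col, dcl1dcl2dcl4 over dcl2dcl4, nrpd1a over Col, Ler MIR845 over Ler, osd1_2 over Ler, osd1_2 MIR845 over osd1_2, and the last MIR845 ratio over that in Ler. With all matched reads they were 4.56, 1.07, 0.233, 0.100, 0.430, 0.0290, 2.71, 2.26, 1.56 and 0.577. With listed miRNAs they were 29.0, 3.94, 0.442, 1.58, 3.57, 0.157, 0.864, 0.617, 1.37 and 1.59; the 4th, 5th, 7th, 8th and last turned direction, and in the dcl1 and dcl1dcl2dcl4 libraries that denominator is itself lower. In the Ler-0 libraries the listed miRNAs leaned on miR166a, at 16080 of 76400 RPM in Ler and 96340 of 186700 in osd1_2. The 7th and 8th turns may thus not hold without miR166a, which was not computed. Uniquely matching reads gave 10.1 for leaf, 0.119 for nrpd1a, 1.66 and 1.42 for the next ratios, 1.32 and 0.794. Without protein-coding genes the values were 12.0, 1.08, 0.371, 0.966 (dcl1dcl2dcl4 over dcl2dcl4, with an interval of 0.907 to 1.03 that holds 1), 0.178, 1.18, 1.09, 1.1 and 0.931. The authors' deposited signal gave 8.54, 1.14, 0.392, 0.316, 0.805, 2.09, 1.58, 1.52 and 0.729, leaving out nrpd1a, which stayed within its interval. For miR845 relative to other listed miRNAs, the ratio was 0.0311 for dcl1, 0.0902 and 0.216 for dcl1dcl2dcl4 over Col and over dcl2dcl4, 56.4 for Ler MIR845 and 0.544 for the ratio of MIR845 ratios, and it turned direction for nrpd1a (1.28) and osd1_2 over Ler (0.875). With ends within 1 nt it was 44.0 for Ler MIR845 and 13.5 for osd1_2 MIR845. With single TE genes the median over all units was 1.46, 1.30 and 1.01 for Ler MIR845, osd1_2 and osd1_2 MIR845, and that of units with the motif turned to 0.971 in osd1_2 MIR845; no such gene reached 200 reads in the leaf, dcl2dcl4, dcl1dcl2dcl4 and nrpd1a comparisons. A minimum of 50 reads kept all 12 medians within their intervals but changed the counts at least 2-fold: 30 against 8 higher in pollen than leaf, 2 against 1 in dcl1, 26 against 8 lower in dcl2dcl4, 28 against 7 in dcl1dcl2dcl4, 28 against 8 in nrpd1a with 3 against 1 higher, and 130 against 22, 70 against 7 and 30 against 1 higher in the Ler-0 comparisons; over dcl2dcl4, 3 families were then lower in dcl1dcl2dcl4 where 0 had been measured. The shares of 21-, 22- and 24-nt reads moved by -13.7 to 22.1 points when distinct sequences were counted and by -4.98 to 15.6 points without organellar and structural RNA. The cause of these shifts was not tested. Depth limits the Col-0 libraries most, where the dcl1dcl2dcl4 library had 116375 reads in its denominator.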

Other observations

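All tests in this part were chosen after the results were seen. The levels of single TE families differed between Ler and Col pollen. Of 49 families measured in Ler and Col sorted pollen, 34 were at least 2-fold lower and 6 at least 2-fold higher in Ler, and the split was 15 and 7 without protein-coding fragments, 11 and 7 with listed miRNAs and 42 and 5 with all matched reads. AT3G29775 was 316 times higher in Ler (75.8 to 2261), AT1G46120 at least 85.3-fold, AT2G05025 47.9 times, AT5G45605 47.4 times and AT3G30815 at least 12.2-fold. On the lower side AT2G09187 had a ratio of 0.138, AT1G40077 0.160 and AT5G28263 0.176. Reads were matched exactly to TAIR10.1 and to no Ler genome. Ler reads that differ from it in sequence were not counted, which can lower the Ler levels. The Col library was also sorted, and the Ler library is not labelled as sorted. TE genes with the motif held 35.9% of 21-22-nt TE reads in Ler and 15.7% in Col sorted pollen. Of the 28197 such reads in Ler, AT3G29775 held 7065 and AT1G46120 3301. miR845b, counted as the identical sequence, was 149-fold lower in Ler.

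AT3G29775 and AT1G46120 gave mostly 21-22-nt reads in Ler, 19.3 and 13.7 times their 24-nt reads, from 1559 and 1612 distinct sequences. Within 500 bp downstream of the motif, Ler pollen held 1268 RPM of sense and 755 RPM of antisense 21-22-nt reads, against 185 and 137 RPM upstream. In Col sorted pollen the downstream levels were 323 and 373 RPM, against 454 and 319 upstream. In nrpd1a pollen they were 36.3 and 24.1 RPM, against 205 and 97.3 upstream. The downstream levels were 1707 and 1292 RPM in Ler MIR845, 1770 and 1210 in osd1_2, and 1704 and 1248 in osd1_2 MIR845. In Ler these windows held 6374 sense and 3795 antisense reads, while AT3G29775 and AT1G46120 held 7065 and 3301 reads in all. Whether the skew holds at motif sites of other families was not tested.

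Families near 0 in Col sorted pollen were abundant in all 4 Ler-0 libraries. Deeper sequencing does not account for them, as at the Ler level the Col library would have held at least 36.6 reads for each of the 5 families, with 0.2 seen for that one. Amplification of a few sequences is argued against as the whole cause. Without the 10 most abundant sequences of each family, the Ler level was still at least 7.31-fold above the whole Col level for AT3G30815, 11.9 times (6.61 to 22.4) for AT5G45605 and 20.1 times (7.84 to 74.0) for AT2G05025, although the 10 held 74.9% and 57.9% of the reads of the last 2 families. AT3G29775 and AT1G46120, with 21.2% and 19.1% in 10 sequences, stood further above. A strain difference in copies of these elements may underlie the pattern and was not tested, since no Ler genome was used here.

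A set of 5 miRNAs (miR166a, miR396b-5p, miR159a, miR390a and miR159b-3p) was not lowered in dcl1 pollen (ratios 0.840 to 1.09), where the other 12 of 17 were at least 3.64-fold lower. The 5 were 3.59 to 17.6 times higher in Ler MIR845 and 5.99 to 19.8 times in osd1_2 than in Ler pollen, against at most 1.73 and 1.68 for the other 12. Both comparisons share the Ler library, so they are not independent. In osd1_2 MIR845 over osd1_2, which does not use it, the 5 had ratios of 0.685 to 2.09 with a median of 0.735, against a median of 1.07 for the other 12. Leaf RNA is argued against as the whole source. Of 9 leaf-abundant miRNAs, 7 were also detected in Col sorted pollen. The 9 include all of the set but miR390a, which goes with leaf RNA. They also include miR157a of the other 12, which was not higher in Ler MIR845 than in Ler (0.885). The median of the 9 implied 5.44% leaf RNA in Ler MIR845, and 2 of the 9 implied a share within 2-fold of it. The share from miR167a (1567 RPM in leaf) was 0.447%, or 0.0822 of the median, while miR166a (173000 RPM) implied 26.5% and miR159a (23110 RPM) 13.3%. Other values go with leaf RNA: TAS1C implied 9.69%, TAS2 7.51% and TAS3 5.59%, all within 2-fold of the median, and plastid reads rose from 0.716% of matched reads in Ler to 2.14% in Ler MIR845 and 4.95% in osd1_2, with 24.3% in leaf. A part from leaf, or RNA of another tissue not profiled here, stays open, as the Ler-0 libraries are not labelled as sorted. No biological explanation was tested.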
